A study of Homo sapiens with 2 samples.

How the data were processed

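U2OS cells were transfected with a pcDNA3.1 plasmid for TERT-WT or TERT-K626A, and double-stranded RNA was captured from 9 µg of total RNA with 5 µg of the J2 antibody before strand-specific library construction, per the labels' protocols. Each group had 1 library, and the groups were taken from the labels. The deposited tables, 1 per strand, hold raw whole-number counts of reads per LTR subfamily, with the copies of a subfamily summed, per the file headers. The submitters' processing notes name STAR, HOMER and the genome build hg38, without versions, roles or settings. How reads that map to several copies were counted is not given in the sources used here, so counts of closely related subfamilies (such as LTR7 and LTR7Y, or the LTR12 elements) may share reads and are uncertain to that extent. The strand of each table is taken as deposited. The coordinates in a row refer to a single copy, and 20 rows had the same coordinates in both tables, so no coordinates are given. Both tables name the same 578 subfamilies, all of the LTR class. LINE, SINE, DNA transposon, SVA, satellite and structural RNA lists, the gene lists and TERT itself were planned but not analysed here.

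Counts were divided by each library's total LTR count over both strands, 1661580 for TERT-WT and 2147463 for TERT-K626A, and scaled to a sum of 1000000 (CPM). These totals hold only the LTR class and are not the depth of the libraries, which is not given in the sources used here. A change shared by all LTR subfamilies would therefore not be seen. Log2 ratios of TERT-WT over TERT-K626A used a prior count of 0.5 in each library, and subfamilies with at least 20 counts over both libraries on a strand were tested, 561 sense and 565 antisense. A size rule of 2-fold was used in place of a test, because 1 library per group allows no estimate of the spread between replicates, and no p-value is given. Intervals of ratios are exact conditional 95% intervals from the Clopper-Pearson interval of the TERT-WT share of the counts, and shares have Clopper-Pearson 95% intervals. They compare these libraries, not the conditions. A count of 0 allows up to 3 counts, or 1.81 CPM in the TERT-WT and 1.40 CPM in the TERT-K626A library, and 5 sense and 2 antisense subfamilies had no counts in either library. The median subfamily had 431 (TERT-WT) and 524.5 (TERT-K626A) sense counts and 524 and 666 antisense counts. The difference between the sense and antisense log2 ratios of a subfamily has an interval from the counting errors of both.

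Each list of subfamilies was described by its median log2 ratio, with its percentile among 10000 random lists of the same size matched on mean level in 10 bins, by the number of members with intervals above or below 1, and by the ratio of its summed counts. Families are those in the tables. The sub-lists were fixed by name before the data were examined. A stem followed by a further digit was read as another subfamily (LTR5, LTR7, LTR12, LTR2, HERVH, HERV9 and HERVE), while every name starting with HERVL was kept in HERV-L. Names ending in -int or -I are internal parts and all others LTR parts. The subfamilies named were, on each strand, those past 2-fold with a mean level at or above the median of the table and intervals excluding 1 (none were), the 5 with the highest mean, those past 2-fold in the same direction on both strands (none were), and up to 4 members of each sub-list by mean level. Those past 2-fold at lower levels, the 8 largest differences in each direction at or above the median level with intervals excluding 1, and subfamilies named for their antisense share were added after their values were seen. Members named beside these, such as LTR7C and LTR7A, were added in the same way.

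The procedure was tested on simulated counts drawn from the real levels and totals with counting error alone. These draws held no spread between libraries, so their shares are not rates of false calls in the real data. There the robust variance of sense log2 ratios was 3.04 times the counting variance in the shallowest and 14.1 times in the deepest depth group. Robust values come from the median absolute deviation, which gives little weight to outlying subfamilies. Of 361 unchanged sense subfamilies, 0% passed 2-fold and 4.16% had an interval excluding 1, and of 365 unchanged antisense subfamilies 0% and 3.56%. All of the 100 subfamilies changed 4-fold passed 2-fold on each strand. For those changed 1.5-fold, the interval excluded 1 in 90% on the sense strand and 95% on the antisense strand. The alternatives tried were ratios centred on the median subfamily, prior counts 10 times larger and smaller, no filter on low counts, subfamilies at or above the median level only, size rules of 1.5-fold and 4-fold, summed counts in place of medians, totals without the 5 highest subfamilies and, added after the data were seen, totals and antisense shares without HERVH-int. The work used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.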

Results

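Double-stranded RNA was profiled in U2OS cells, a human osteosarcoma line that maintains its telomeres without telomerase, after transfection for 48 h with a plasmid for wild-type telomerase reverse transcriptase (TERT-WT) or for the substituted form TERT-K626A. RNA bound by J2, an antibody against double-stranded RNA, was sequenced with the strand kept. There was 1 library per group, so each difference between the groups has no replicate check, and no control library without TERT was analysed here. No library of RNA before J2 capture was analysed either. A ratio therefore cannot separate the level of a transcript from the part of it in double-stranded form. The series title names the activation of endogenous retroviruses by TERT, and the comparison asks whether retroviral RNA in the J2 fraction differed between the TERT forms. The deposited counts cover 578 repeat subfamilies of the long terminal repeat (LTR) class on each strand. Each subfamily sums its copies over the genome (median 458, from 1 to 22935, and 748597 in all), so a value is not tied to a position. The counts do not show how reads spread over these copies. Nor do they show whether the reads came from retroviral transcripts or from host transcripts that contain a repeat. The TERT-WT library held 856756 sense and 804824 antisense counts over these subfamilies, and the TERT-K626A library held 1116045 and 1031418. The TERT-WT totals were therefore 0.768 times those of TERT-K626A on the sense strand and 0.780 times on the antisense strand, which can reflect sequencing depth alone because the full depth of the libraries was not used here. All levels are counts scaled so that a library's LTR counts over both strands sum to 1000000 (CPM), and ratios are TERT-WT over TERT-K626A. Intervals are 95% and cover counting error only, since 1 library per group gives no spread between libraries. They take each read as an independent molecule and are too narrow where reads are not.

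On the sense strand, HERV-H reads were lower in the TERT-WT library. HERVH-int, the internal part of the HERV-H proviruses (5967 copies), had 80194 counts with TERT-WT and 146872 with TERT-K626A, or 48264 against 68393 CPM, and was 1.42-fold higher with TERT-K626A (interval 1.41 to 1.43). LTR7 and LTR7Y, LTRs that flank and promote HERV-H, went the same way, with log2 ratios of −0.52 and −0.64, while LTR7B was at 0.07 and LTR7C at −0.01, both with intervals that included 1. Summed over the group, sense HERV-H reads made up 5.36% of all LTR counts with TERT-WT and 7.57% with TERT-K626A, 1.41-fold higher with TERT-K626A (interval 1.40 to 1.42). The median of the 5 tested members was −0.50, at percentile 0.005 among 10000 random lists of subfamilies matched on mean level. The random lists draw unrelated subfamilies, while HERVH-int, LTR7 and LTR7Y are parts of the same provirus group, and LTR7 and LTR7Y may share reads. The percentile can therefore overstate rarity, and the same limit holds for the other provirus groups below. 3 of the 5 had intervals below 1 and none above. With LTR7A included (10 and 6 counts, too few to be tested), the median was −0.26.

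The HERV9 group, whose LTR12 elements are known promoters in human cells, was also lower with TERT-WT on the sense strand, with a median log2 ratio of −0.14 (percentile 0.13). LTR12C had 23208 and 35337 counts, 1.18-fold higher with TERT-K626A (interval 1.16 to 1.20), and HERV9NC-int was at −0.17. LTR12 went the other way, at 0.25, and LTR12D was at −0.01. Of the 10 members, 4 had intervals below 1 and 1 had an interval above it.

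Both members of HERV-W, the group that includes the syncytin-1 locus, were higher in the TERT-WT library on the sense strand, with HERV17-int at a log2 ratio of 0.30 and LTR17 at 0.38 (1.30-fold, interval 1.22 to 1.37), and their median stood at percentile 99.3. As linked parts of the same provirus group, they do not count as separate members. In the HERV-K/HML-2 group, the youngest human proviruses, the internal part HERVK-int was 1.24-fold higher with TERT-WT (interval 1.19 to 1.28), while its LTRs LTR5_Hs and LTR5A were at 0.02 and 0.01 and LTR5B was at −0.24. HERV-K/HML-2 had a median of 0.01 (percentile 21.7; −0.08 when ratios were centred on the median subfamily), with 1 member's interval above 1 and 2 below. HERVE-int was at 0.29, and the HERV-E median was 0.13 (percentile 68.7), with 2 of 5 intervals above 1 and none below. In the list of names starting with HERVL or MLT2, 11 of 18 members had intervals above 1 and 3 had intervals below, with HERVL-int at 0.32 and MLT2B4 at −0.22. It also holds numbered HERVL internal parts, such as HERVL18-int at 0.90 and HERVL40-int at 0.15, so it is wider than HERV-L with its MLT2 LTRs. The median of this list, 0.11, stood at percentile 70.8. The medians of HERV-K/HML-2, of HERV-E and of the HERVL and MLT2 names thus lay within the central 95% of random lists.

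The older ERVL-MaLR elements took large shares of the counts. Of 78 tested sense subfamilies, 34 had intervals above 1 and 10 below, the latter including MST-int at −0.34 and MSTA1 at −0.48. Over all 561 tested sense subfamilies, 206 intervals lay above 1 and 67 below. The ERVL-MaLR median of 0.06 was lower than the 0.09 of all these subfamilies, so the split does not set this family apart. MSTA-int and MSTA, with 32145 and 19909 CPM in the TERT-WT library, were 1.14-fold (interval 1.12 to 1.15) and 1.14-fold (1.12 to 1.15) higher there, and the MST median was 0.09. MLT1D was at −0.07 and THE1B at −0.03, and the medians of MLT1 and THE1 were 0.06 and 0.05. These medians lay within the central 95% of random lists and turned negative when ratios were centred on the median subfamily. MER41 elements, some of which act as interferon-inducible enhancers, had a median of 0.04, with MER41B at 0.19, MER41-int at −0.06 and MER41C at −0.32, and this median too turned negative with that centring. By family, the sense medians were 0.11 for ERV1, 0.12 for ERVK, 0.10 for ERVL, 0.06 for ERVL-MaLR and 0.06 for Gypsy, none of them outside the central 95% of random lists. Those of ERVL-MaLR and Gypsy turned negative with the same centring. The summed ERV1 counts gave a log2 ratio of −0.15, opposite in sign to the ERV1 median, and sense HERVH-int reads alone made up 4.83% of all LTR counts with TERT-WT and 6.84% with TERT-K626A.

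**Figure D1:**
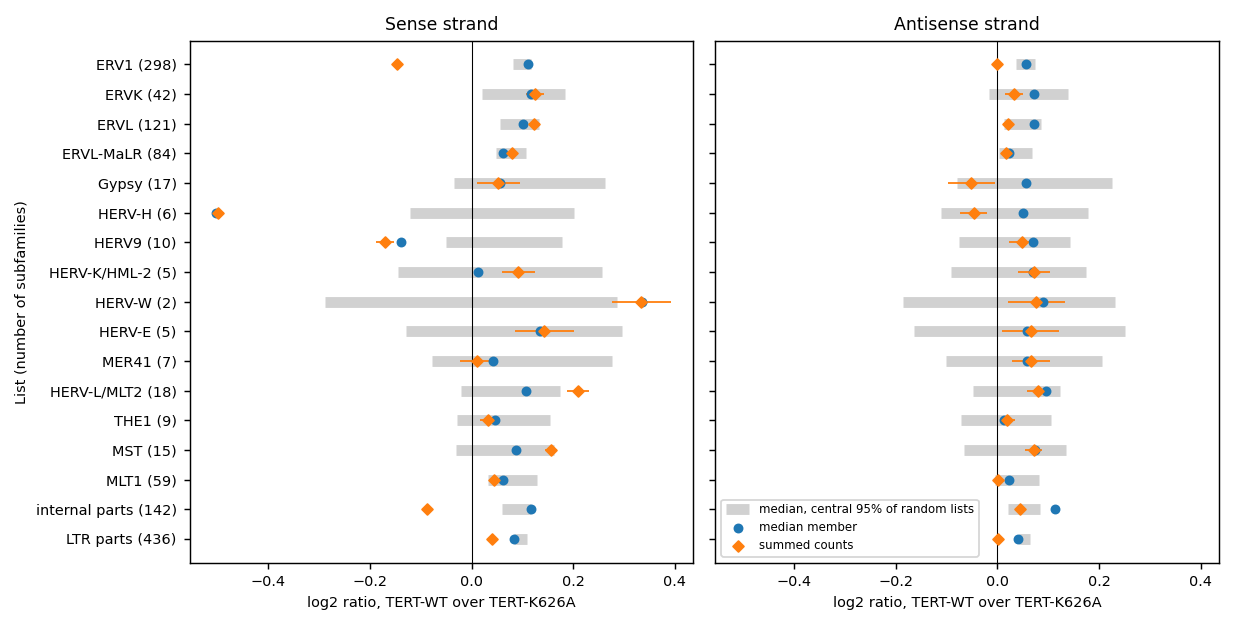
Log2 ratio of TERT-WT over TERT-K626A (horizontal axes) for each list of subfamilies (rows, with the number of subfamilies) on the sense (left) and antisense (right) strand. Blue points are medians over tested members, orange diamonds are ratios of summed counts with 95% counting intervals, and grey bars span the central 95% of medians of 10000 matched random lists. HERV-H stands at −0.50 on the sense strand and at 0.05 on the antisense strand.

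On the antisense strand, the medians of the same groups lay closer together, between 0.01 and 0.10. HERVH-int had 15670 and 21442 counts, a log2 ratio of −0.08 (1.06-fold higher with TERT-K626A, interval 1.04 to 1.08), and LTR7, LTR7Y and LTR7B were at 0.05, 0.14 and 0.09. The HERV-H median was 0.05 (percentile 54.0), although summed counts gave −0.05. The HERV9 median was 0.07 and became 0.01 when centred on the median subfamily, with LTR12C at 0.04 before centring and −0.02 after it. HERV-W stood at 0.09, HERV-E at 0.06 and HERV-K/HML-2 at 0.07, with LTR17 at 0.18, LTR2 at 0.35, HERVK-int at 0.14 and LTR5_Hs at 0.07. For the list of HERVL and MLT2 names, 10 of 18 intervals lay above 1 and none below, with a median of 0.10 and HERVL-int at 0.21. The MST, MLT1, THE1 and MER41 medians were 0.07, 0.02, 0.01 and 0.06. MLT1D, MLT1C and MLT1A0, the subfamilies with the highest antisense levels, were at 0.02, −0.00 and −0.03, and MSTA-int at 0.23, while MLT-int, with 308 and 571 counts, was at −0.52. The family medians ran from 0.02 for ERVL-MaLR to 0.07 for ERVL, and those of ERVL-MaLR, HERV-H, THE1 and MLT1 turned negative when centred on the median subfamily.

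Internal parts and LTR parts differed slightly in their medians. The median was 0.12 over 134 tested internal parts on the sense strand (percentile 97.3) and 0.11 over 138 on the antisense strand (percentile 99.99). The LTR parts, 427 tested on each strand, had medians of 0.08 (percentile 4.99) and 0.04 (percentile 1.74). Both sense medians lay within the central 95% of random lists and both antisense medians outside it. LTR parts are all subfamilies other than internal parts, so these percentiles express a single contrast per strand. Summed sense counts of internal parts went the other way, at −0.09, and the LTR part medians turned negative on both strands with ratios centred on the median subfamily.

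No subfamily with a mean level at or above the median of its table differed by 2-fold on either strand. Among 561 sense subfamilies with at least 20 counts over both libraries, 10 were at least 2-fold higher and 2 at least 2-fold lower with TERT-WT. These 12 held 27 to 207 counts over both libraries (median 75.5), and their names follow from values seen, not from a list fixed in advance. LTR81AB had 39 and 14 counts, 3.52-fold higher (interval 1.91 to 7.18), MER101B was 2.85-fold and MER50C 2.32-fold higher, and LTR22C2, an ERVK LTR with 24 and 88 counts, was 2.79-fold higher with TERT-K626A (interval 1.79 to 4.66). Of the 10 higher ones, HERV1_LTRe had an interval that included 1. Among 565 antisense subfamilies, HERVK14C-int was 3.54-fold higher with TERT-WT (42 and 15 counts, interval 1.97 to 7.03), HERV1_LTRc was 2.65-fold higher, and none was 2-fold lower. Without the minimum of 20 counts, 7 sense subfamilies were 2-fold lower, and 7 antisense subfamilies were 2-fold higher and 5 lower. Most ratios were small: 515 sense subfamilies (91.8%) and 545 antisense subfamilies (96.5%) lay within 1.5-fold. The median log2 ratio over all tested subfamilies was 0.09 on the sense and 0.06 on the antisense strand.

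Below the 2-fold rule, the largest differences at or above the median level, again chosen after their values were seen, were on the sense strand HERVL18-int, with 4635 and 3218 counts and 1.86-fold higher with TERT-WT (interval 1.78 to 1.95), followed by LTR18C at a log2 ratio of 0.65, LTR53-int at 0.58 and LTR48 at 0.55. In the other direction, HERVIP10FH-int had 5931 and 13694 counts and was 1.79-fold higher with TERT-K626A (interval 1.73 to 1.84), and LTR10F and HERVIP10F-int were at −0.74 and −0.56. LTR7Y, LTR7 and HERVH-int, with the values given for HERV-H, also ranked among these, ahead of MSTA1 at −0.48. On the antisense strand, LTR43-int was 1.94-fold higher with TERT-WT (1574 and 1050 counts, interval 1.79 to 2.10) and LTR43 was at 0.52. LTR39 was 1.62-fold higher with TERT-K626A (7161 and 15001 counts, interval 1.58 to 1.67), with LTR10B1 at −0.58, HERVIP10B3-int at −0.53 and MER4A at −0.46. Intervals lay above 1 for 206 sense subfamilies and below 1 for 67, and for 171 and 96 on the antisense strand. With ratios centred on the median subfamily, the split was 114 above and 120 below on the sense strand and 103 above and 137 below on the antisense strand, a near balance that this centring imposes by construction. With totals that leave out HERVH-int, a scale added after the data were seen, 164 sense intervals lay above 1 and 80 below, and 135 and 117 antisense ones.

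**Figure D2:**
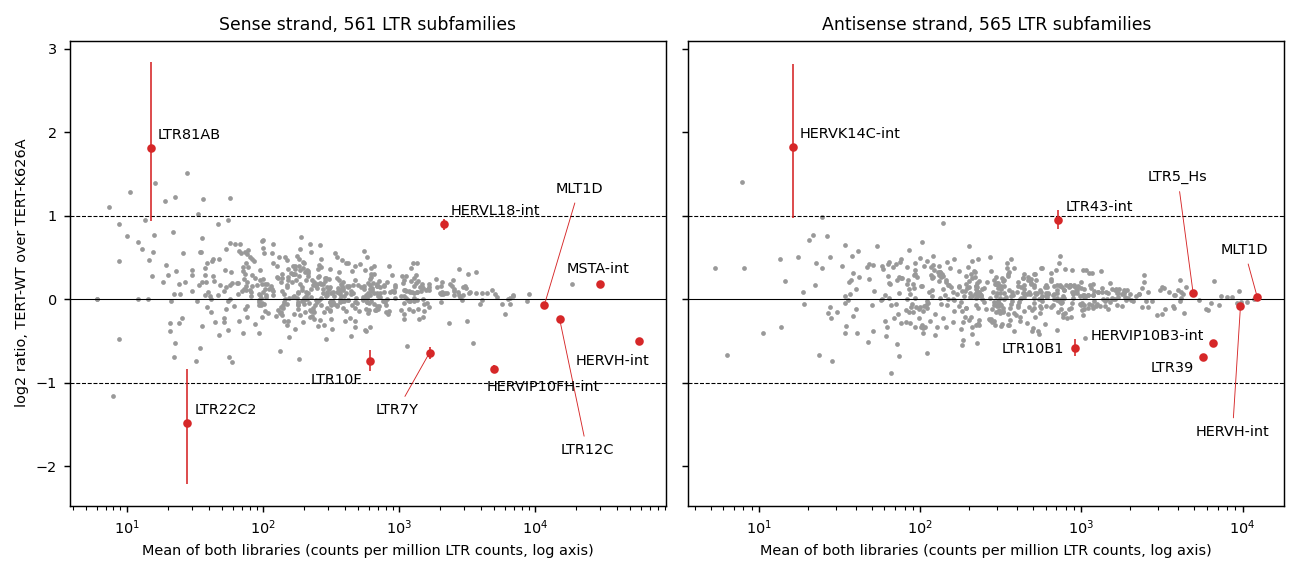
Log2 ratio of TERT-WT over TERT-K626A (vertical axis) against the mean level of both libraries in CPM (horizontal log axis) for 561 sense (left) and 565 antisense (right) subfamilies, 1 point each. Red points are named, with 95% counting intervals as vertical lines, and dashed lines mark 2-fold. HERVH-int is the rightmost point on the sense strand at −0.50, and the points past 2-fold lie at low levels.

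No subfamily was past 2-fold in the same direction on both strands among 557 tested on both, where independent lists would give 0.0359 higher and 0 lower. HERV1_LTRc, named after its values were seen, was past 2-fold in opposite directions, with 8 and 24 sense counts (2.23-fold higher with TERT-K626A, interval 1.01 to 5.98) and 19 and 9 antisense counts (2.65-fold higher with TERT-WT, interval 1.18 to 6.85). At 1.5-fold, 4 were higher on both strands, against 0.711 for independent lists: HERV1_LTRe, HERVFH21-int, LTR18C and LTR43-int, named after their values were seen. MLT1L-int was 1.5-fold lower on both strands, against 0.118 for independent lists. Both strands come from the same libraries, so part of such overlap can come from their shared scale. The values for independent lists also take every subfamily as equally likely to pass. Ratios spread more at low counts, with a robust sense SD of 0.421 in the shallowest and 0.129 in the deepest depth group. The values for independent lists can therefore be too low. Across the 557 subfamilies, which are not independent replicates, the sense and antisense log2 ratios had a Pearson correlation of 0.17 and a Spearman correlation of 0.20. Over the 240 subfamilies at or above the median level on both strands, the Pearson and Spearman correlations were 0.14 and 0.12. The strands also parted within groups: the sense log2 ratio minus the antisense one was −0.42 for HERVH-int (interval −0.45 to −0.39) and −0.79 for LTR7Y.

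Antisense reads made up 48.4% of the LTR counts of the TERT-WT library (exact binomial interval 48.4 to 48.5) and 48.0% of those of the TERT-K626A library (48.0 to 48.1). Without HERVH-int, left out after the data were seen, the shares were 50.4% and 51.0%, so the order of the libraries reversed. Subfamilies differed widely in this share. Antisense reads were 12.1% of MSTA-int counts with TERT-WT and 11.8% with TERT-K626A, 16.3% and 12.7% of HERVH-int counts, and 9.40% and 5.71% of LTR46-int counts. High shares were seen in HERV1_I-int with 93.5% and 94.7%, LTR43-int with 91.0% and 88.7%, and LTR39 with 84.6% and 88.7%. MLT1D, with 52.0% and 50.4%, and THE1B, with 52.9% and 53.0%, were close to even. The median subfamily had 55.6% with TERT-WT and 56.4% with TERT-K626A over 565 subfamilies. Shares of the same subfamily were close in both libraries, with a Pearson and a Spearman correlation of 0.95 across subfamilies and a median difference of 1.01 percentage points (TERT-K626A minus TERT-WT, 5th to 95th percentile −7.73 to 8.86). In the ERV1 family as a whole, antisense reads were 42.5% with TERT-WT and 40.0% with TERT-K626A. Most of this gap came from HERVH-int, without which the shares were 47.2% and 46.7%, and the median ERV1 subfamily ran the other way with 54.4% and 55.9%. The summed share was higher with TERT-K626A in ERVL (55.7% and 57.5%), ERVL-MaLR (51.0% and 52.1%) and ERVK (50.1% and 51.7%). LTR48 stood at 56.7% with TERT-WT and 70.3% with TERT-K626A, and LTR70 at 51.1% and 38.9%.

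**Figure D3:**
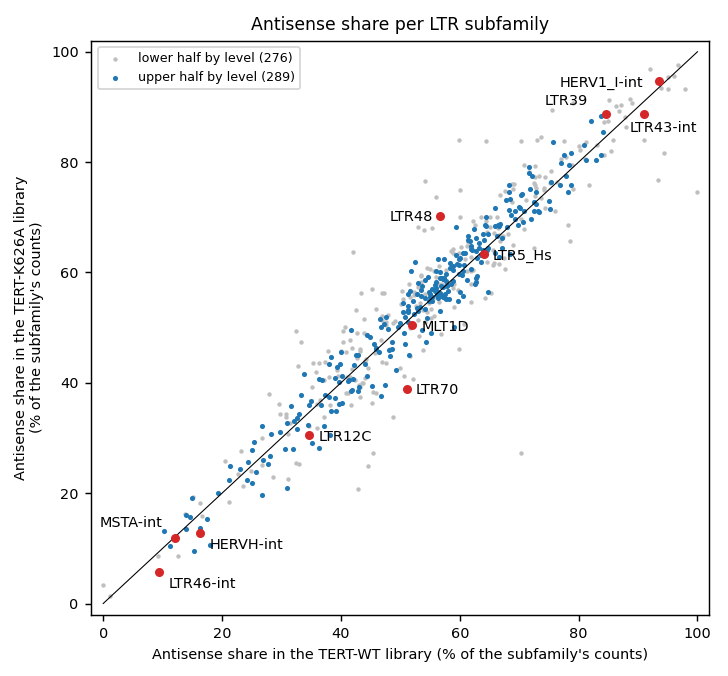
Antisense share of each subfamily's counts in percent, TERT-WT library (horizontal axis) against TERT-K626A library (vertical axis), for 565 subfamilies, 1 point each. Blue points are at or above the median level and grey points below it, red points are named, and the diagonal marks equal shares. Points follow the diagonal, and those at or above the median level run from LTR46-int at 9.40% and 5.71% to HERV1_I-int at 93.5% and 94.7%.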

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

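Centring on the median subfamily subtracts 0.0900 (sense) or 0.0556 (antisense) from each log2 ratio, which by construction moves or reverses small ones. List medians are called reversed only where the sign changed and their counting interval excluded 0. The sign of others, such as sense HERV-K/HML-2 and antisense THE1 and MLT1, also changed, but their intervals included 0. Sense medians became 0.021 for ERV1, 0.026 for ERVK, 0.0118 for ERVL, −0.0775 for HERV-K/HML-2, −0.593 for HERV-H, 0.245 for HERV-W, −0.23 for HERV9, 0.017 for HERV-L/MLT2 and 0.027 for internal parts, and reversed to −0.028 for ERVL-MaLR, −0.0332 for Gypsy, −0.0442 for THE1, −0.00277 for MST, −0.028 for MLT1 and −0.00558 for LTR parts. Antisense medians became 2.86e-05 for ERV1, 0.016 for ERVL, 0.0139 for HERV-K/HML-2, 0.0336 for HERV-W, 0.0142 for HERV9, 0.0402 for HERV-L/MLT2, −0.0429 for THE1, −0.0333 for MLT1 and 0.0584 for internal parts, and reversed to −0.0329 for ERVL-MaLR and −0.0145 for LTR parts. MLT1A0 (−0.0366), MLT1C (−0.0274), THE1B-int (−0.0522) and THE1D-int (−0.0215) reversed on the sense strand and LTR12C (−0.0185) on the antisense strand. Only named ratios whose counting interval excluded 1 are listed here, and the sign also changed in 7 named sense and 6 named antisense ratios whose interval included 1. Totals without HERVH-int, an alternative chosen after seeing the data, gave sense medians of 0.0789 for ERV1, 0.0698 for ERVL, 0.0300 for ERVL-MaLR, −0.535 for HERV-H, 0.0137 for THE1, 0.0300 for MLT1, 0.0849 for internal and 0.0524 for LTR parts, and antisense medians of 0.0237 for ERV1, −0.00926 for ERVL-MaLR (reversed), −0.00969 for MLT1 and 0.00917 for LTR parts. Neither scale moved a count past 2-fold by over 1.5 times. A prior 10 times larger left 1 sense subfamily 2-fold lower. Without the filter on low counts, 7 sense subfamilies were 2-fold lower, 7 antisense higher and 5 antisense lower, with 1 higher and 1 lower on both strands (MLT1E1-int and MLT1E-int, with at most 2 counts in any library), and the HERV-H sense median was −0.257. Among subfamilies at or above the median level, the sense counts were 0 higher and 0 lower and the antisense count 0 higher, the ERV1, MST and internal part sense medians were 0.0835, 0.0407 and 0.0789, the Gypsy antisense median −0.0561, and the Spearman correlation between strands 0.118. At 1.5-fold, 34 sense subfamilies were higher and 12 lower, 13 antisense higher and 7 lower, and 4 and 1 on both strands. At 4-fold, there were 0 sense higher, 0 sense lower and 0 antisense higher. Summed counts gave on the sense strand −0.146 for ERV1 and −0.0876 for internal parts (both reversed), 0.0793 for ERVL-MaLR, 0.0923 for HERV-K/HML-2, 0.209 for HERV-L/MLT2, 0.156 for MST and 0.0412 for LTR parts, and on the antisense strand −0.000655 for ERV1 (reversed), 0.0215 for ERVL, −0.0512 for Gypsy, −0.0471 for HERV-H, 0.0449 for internal and 0.00191 for LTR parts. Without HERVH-int, an alternative chosen after seeing the data, the summed sense ratios were 0.0690 for internal parts, back at the sign of the median, and −0.0235 for ERV1, still reversed but nearer 0, and the antisense ones 0.0565 for internal parts and 0.00467 for ERV1. Totals without the 5 highest subfamilies gave ratios of 0.800 (sense) and 0.783 (antisense). The antisense share was 56.0% and 56.2% at or above the median level, 48.4% and 48.0% summed, and 50.4% and 51.0% without HERVH-int (TERT-WT and TERT-K626A), so the order of the summed shares reversed. The summed ERV1 share without HERVH-int, also chosen after seeing the data, was 47.2% and 46.7%, in place of 42.5% and 40.0%. With either prior, no list median and none of the 119 named log2 ratios moved beyond its counting interval. Low counts limit the calls past 2-fold, which held at most 207 counts. Totals without structural RNA, satellites and simple repeats were not run, since the tables hold the LTR class.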

Other observations

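The tests of HERV-H, of counting error alone and of copy length among internal parts were chosen only after the results were seen.

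Some HERVIP10 and LTR10 subfamilies, ERV1 internal parts and LTRs picked here by name after their values were seen, were higher with TERT-K626A. They were not a fixed list and had no enrichment test. All 3 HERVIP10 subfamilies had sense intervals below 1, and 2 of the 3 had antisense intervals below 1. Of the 9 LTR10 subfamilies, 6 had sense log2 ratios above 0 and 3 below (intervals above 1 for 3 and below 1 for 2), and 3 had antisense ratios above 0 and 6 below (intervals above 1 for 1 and below 1 for 2). On the sense strand, HERVIP10FH-int, HERVIP10F-int and LTR10F had log2 ratios of −0.84, −0.56 and −0.74, and on the antisense strand of 0.04, −0.11 and 0.02. HERVIP10B3-int and LTR10B1 had antisense ratios of −0.53 and −0.58 and sense ratios of −0.28 and −0.04. The sense minus antisense difference was −0.88 for HERVIP10FH-int (counting interval −0.99 to −0.77) and 0.54 for LTR10B1, and 0.52 for LTR39 (0.42 to 0.63), another ERV1 LTR with mostly antisense reads. LTR10A, LTR10B, LTR10B2, LTR10D, LTR10E and LTR10G went the other way on the sense strand, at 0.16, 0.08, 0.90, 0.04, 0.18 and 0.06.

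Per kilobase of annotated copies, HERVIP10B3-int had 19.8 CPM with TERT-WT and 27.3 with TERT-K626A over both strands, HERVK13-int 21.5 and 22.0, and LTR7Y 16.9 and 24.7. HERV1_LTRa with 24.8 and 18.3 and LTR4 with 20.7 and 15.5 were higher with TERT-WT. The median subfamily had 3.05 and 2.90. Across 567 subfamilies, which are not independent replicates, this density had a Spearman correlation of −0.28 with the divergence of the copies in both libraries. Within families it was −0.22 (TERT-WT) and −0.24 (TERT-K626A) in ERV1, −0.16 in both libraries in ERVL, and −0.20 and −0.21 in ERVL-MaLR, but −0.03 and 0.03 in ERVK and 0.16 and 0.35 in Gypsy.

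HERV-H sense reads were lower with TERT-WT. A scale difference between the libraries would shift all subfamilies alike, so it is argued against as the whole cause, because the summed HERV-H log2 ratio lay −0.588 from that of the median sense subfamily. The summed sense ratio lay below the antisense ratio by −0.451 (counting interval −0.480 to −0.422), but this interval leaves out differences between single libraries, so less HERV-H duplex with both strands recovered alike cannot be told apart from other causes. A different level of HERV-H RNA cannot be told apart either, since RNA before J2 capture was not analysed. A difference between single libraries that is unrelated to the TERT form cannot be told apart from an effect of TERT, since there was 1 library per group. The TERT form stays open, as untested.

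Of the sense subfamilies, 12 were past 2-fold. Draws of unchanged subfamilies with counting error alone gave a mean of 0.806 (central 95% 0 to 3), but this decides nothing about the cause, since separately prepared libraries differ by more than counting error in any case. The 2 antisense ones lay within the 0 to 2 of the draws. A constant number of reads per original fragment would inflate the variance alike at every depth, which is argued against as the cause of the whole spread. Robust variance over counting variance was 3.04 in the shallowest and 14.1 in the deepest of 5 depth groups of sense subfamilies, a ratio of 4.65. Ordinary SDs, which outlying subfamilies raise, were 0.538 and 0.217 in these groups, against counting SDs of 0.241 and 0.0342. Clumped reads may still contribute among low-count subfamilies. A difference between single libraries and the TERT form stay open, as untested.

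LTR parts are all subfamilies other than internal parts, so their medians give a single contrast per strand. Internal parts had a higher median ratio than LTR parts on the antisense strand, where both medians lay outside the central 95% of random lists. On the sense strand the order was the same, but both medians lay within it and summed counts of internal parts went the other way, so the sense difference was not set apart from random lists. If longer repeats were recovered better in the TERT-WT library, ratios would rise with copy length within LTR parts, but the Spearman correlations were −0.0658 (sense) and −0.00499 (antisense). LTR parts were short (median 322 bases sense and 321 antisense) and internal parts longer (638 and 644), so these correlations cannot decide for internal parts. Within internal parts the Spearman correlations were 0.121 and 0.157, too close to the bound of 0.1 to decide. Length among internal parts thus cannot be told apart from other causes. Within a shared window of mean copy length (362 to 520 bases sense, 357.5 to 520 antisense), the difference of medians went from 0.033 to 0.023 on the sense strand and from 0.073 to 0.048 on the antisense strand. The window kept 37 of 134 internal and 118 of 427 LTR parts on the sense strand. On the antisense strand it kept 38 of 138 and 125 of 427. Most internal parts were thus left out, and lengths were not matched pair by pair. The TERT form stays open, as untested.

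A hypothesis set before its test was that the LTR and the internal part of a provirus move together, as shared proviral transcripts would have it. Over 116 pairs matched by name on both strands, their log2 ratios had a Spearman correlation of 0.273, at percentile 99.83 of random matchings. Most proviruses entered on both strands, and the random matchings treated these pairs as independent, so the pooled percentile can overstate rarity. Many pairs were MLT1, MST or THE1 elements. Parts with unlike names, such as HERVH-int and LTR7 or HERV17-int and LTR17, were not paired, so the result does not cover them. By strand it was 0.377 over 59 antisense pairs (percentile 99.95) and 0.158 over 57 sense pairs (percentile 88.2), within the −0.269 to 0.279 of random matchings. The pooled value passed the bound set before the test, but of the strands alone only the antisense pairs passed it. Proviral transcripts would give sense reads, so the pooled value cannot decide whether they contribute. The difference between strands was not tested, and reads that span both parts could also raise the correlation.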
